A study of Homo sapiens and Mus musculus with 41 samples.

How the data were processed

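The series measured polyadenylated RNA in 41 libraries of cultured tumour cells from 4 models: HCC1954 and MDA-MB-231, human breast carcinoma lines; PC9, a human lung adenocarcinoma line; and LLC, the Lewis lung carcinoma line of the mouse. Each model had 4 stages. Par is the parental line, Int an intermediate stage derivative, Lep the leptomeningeal metastatic derivative and BrM a brain metastatic derivative. The numbers of Par, Int, Lep and BrM libraries were 3, 2, 3 and 2 in HCC1954, 3, 2, 2 and 3 in MDA-MB-231 and in PC9, and 3, 2, 3 and 3 in LLC. Per the labels, libraries were made from 500 ng of RNA with the TruSeq RNA v2 kit and read paired-end on a HiSeq instrument, with reads of 75 bases for MDA-MB-231 and 50 bases for the other models. The Par replicates are described as technical, and the Int and Lep replicates as a mixture of biological and technical ones, without saying which is which. The p-values below therefore measure the spread between these libraries, not between independent animals.

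The authors deposited 1 table of normalized counts per model, with genes named by symbol and no coordinates. As deposited by the authors, these signal values are read counts divided by 1 size factor per library. Within each library every deposited value was a whole multiple of 1 step (tolerance 0.01), so whole read counts could be recovered, and DESeq2 size factors recomputed from those reads matched the deposited scaling with a deviation of 0% in each table. The submitters' notes name FastQC 0.11.3, HTSeq 0.5.4 and DESeq2, and the builds GRCh37 (hg19) and GRCm38 (mm10), with no order or role. The aligner is not given in the sources used here. The tables were normalized separately, so every test stayed within 1 model, and no difference between models was tested. Recovered totals ran from 25330801 to 67367833 reads per library in HCC1954, from 23508951 to 110830546 in MDA-MB-231, from 16792027 to 38432963 in PC9 and from 18029707 to 67939274 in LLC. Some lie outside the range of read pairs that the labels give. Within-group spread exceeded counting noise in every pair of replicates: the chi-square per degree of freedom ran from 1.53 (HCC1954 Par replicates 2 and 3) to 454 (MDA-MB-231 Par replicates 1 and 3). A gene at 0 in a library may still have had up to 3 reads there by counting error alone.

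Genes with a value of at least 10 in at least 2 libraries of a model were tested with limma 3.58.1 (trend) in R 4.3.3 on log2(value + 1), with all libraries of the model in 1 fit. Because the deposited values themselves are not whole numbers, this test stayed the main one, and edgeR on the recovered reads an alternative. The 5 comparisons per model were Lep with Par, Lep with Int, Int with Par, BrM with Par and Lep with BrM. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 and its log2 fold change at least 1 in size. All tests are two-sided unless stated. Log2 fold changes are given ± their standard error and group means, in normalized counts, ± SD over the libraries of the group. Where every library of the lower group is at 0, means are given and no fold. On data simulated from these tables with changed genes added, the test of Lep with Par recovered 98.5%, 70.1%, 89.6% and 89.6% of genes changed 4-fold in HCC1954, MDA-MB-231, PC9 and LLC, with 0, 11, 1 and 6 false calls.

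The comparisons, the filter, the thresholds, the gene lists and the rule for named genes were fixed before the data were examined. The 18 gene lists were complement system, iron handling, NF-kB target and cytokine genes, interferon-stimulated genes, antigen presentation, epithelial genes, mesenchymal genes, collagens and matrix, genes reported for brain metastasis derivatives, proliferation, hypoxia and glycolysis, cholesterol and fatty acid synthesis, amino acid and endoplasmic reticulum stress, TGF-beta and YAP target genes, p53 target genes, drug and redox defence, cell adhesion and integrins, and semaphorins, ephrins and axon guidance. The brain metastasis list comes from work on derivatives of this kind and may have been chosen on the same lines. A further 6 lists held markers of host cells: macrophage and microglia, meningeal fibroblast and pericyte, endothelium, lymphocyte, neural and glial, and choroid plexus and ependyma. In human models host cells would be mouse cells, which counts of human genes do not measure. Each list with at least 5 tested members was tested with camera (preset correlation 0.01), adjusted over the 24 lists of a comparison. Alternatives were camera with an estimated correlation, camera with a replicate block, and fry, which asks whether the genes of a list move on balance 1 way.

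Named genes are those called with complete separation of the libraries and a mean of at least 100 in the higher group: the 8 largest changes in each direction in Lep with Par and the 4 largest in the other comparisons. To these were added up to 4 called members of each list in Lep with Par and in any comparison where the list passed, up to 12 genes per count across models, and C3, LCN2 and SLC22A17 in every model, ERBB2 in HCC1954 and EGFR in PC9. SLC22A17 stayed below the filter in MDA-MB-231 and PC9. Any other gene was chosen after its values were seen. Reads of close paralogs (C4A and C4B, SAA1 and SAA2, HLA genes, keratins, AKR1C genes, UGT1A exons, GSTM1) can be shared, so their levels are uncertain. Counts across models matched mouse to human symbols without regard to case and were set against 10000 draws (1000 for pairs of models) that permuted the calls within 10 bins of mean level.

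Alternatives fixed beforehand were a pseudocount of 0.5 or 8, no filter or a filter at 50, quantile normalization, TMM scaling, a fit of the 2 compared groups only, a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and leaving out each library in turn. A group left with 1 library was assumed to vary like the other groups. The replicate block pairs libraries by number and was run in every comparison. Residuals of like-numbered libraries correlated most in MDA-MB-231 Par and BrM (0.50, 0.26 and 0.23 for replicates 1, 2 and 3). Par 3 matched BrM 2 best. After the data were seen, a correction for transcript length and GC content was added for the human models, alone and with the replicate block. It removes from each library the part of its deviation from the gene means that splines of length and GC predict. Lengths and GC came from GENCODE v29 transcripts matched by symbol, for 95.1%, 95% and 95.4% of the genes tested in HCC1954, MDA-MB-231 and PC9. Data were simulated with a length bias and changed genes. The correction lowered false calls from 3636 to 36, from 3344 to 8 and from 3423 to 29. After it 186 of 190, 133 of 190 and 180 of 189 changed genes were recovered, in HCC1954, MDA-MB-231 and PC9. No mouse transcripts were at hand for LLC. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No deposited column was left out.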

Results

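The libraries profile tumour cells at 4 stages in 4 models. GFP-expressing derivatives were rinsed from the leptomeningeal space of mice, grown in culture to a uniform GFP-positive population and passaged before RNA was taken, so the comparisons describe cultured cells. Lep with Par asks which genes differ after growth in the leptomeninges. The Int libraries were the deepest in HCC1954, with 67210373 to 67367833 reads, in MDA-MB-231 (96283309 to 110830546) and in LLC (67198962 to 67939274).

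**Figure D1:**
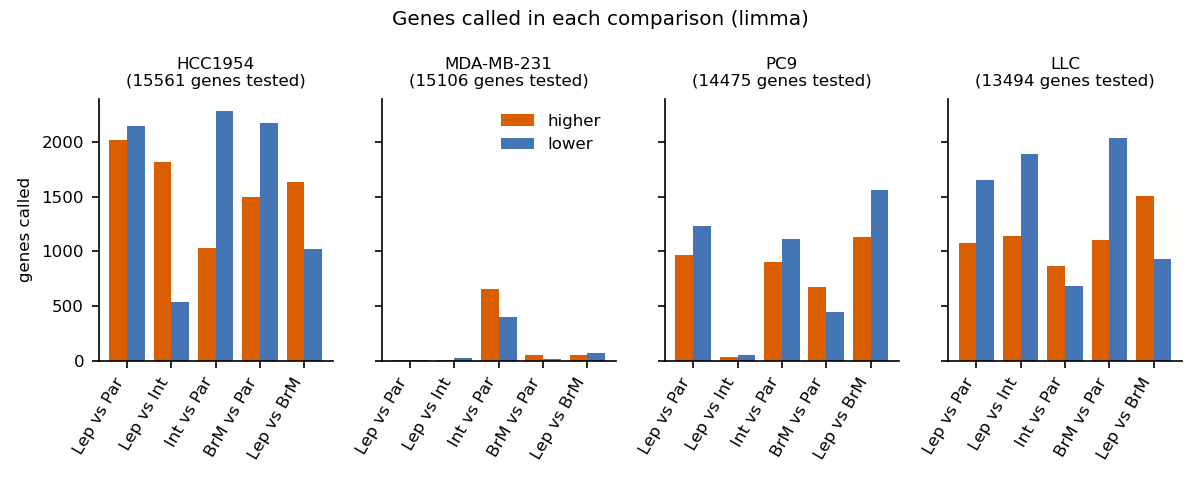
Genes called higher or lower by limma in each comparison of each model, as bars from 0 on 1 shared axis of gene counts.

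In HCC1954, the line whose labels name raised HER2, Lep cells (n = 3) carried 5200 ± 456 normalized counts of IDO1, the enzyme that starts tryptophan breakdown, against 22.3 ± 2.57 in Par (n = 3), a log2 fold change of 7.80 ± 0.12. OLFM4, a secreted glycoprotein, rose from 6.86 ± 2.15 to 17900 ± 2480, and SOX11, a developmental transcription factor, by 8.27 ± 0.24 on the log2 scale. GSTP1, a glutathione transferase that detoxifies electrophiles, had a mean of 8.72 ± 5.9 in Lep against 15300 ± 377 in Par. LDHB, a lactate dehydrogenase subunit, had means of 11.9 ± 11.2 and 17900 ± 407 (-10.77, and -11.44 without Lep replicate 2). INA, a neurofilament subunit, and TUSC3 were listed at 0 in every Lep library, with Par means of 2020 ± 37.8 and 1640 ± 64.9. In all, 2016 genes were called higher and 2149 lower of 15561 tested, a higher share of 48.4% that was 53.8% with quantile normalization.

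Inflammatory genes rose in HCC1954 Lep. Of 27 NF-kB target and cytokine genes tested, 17 rose and 3 fell (median log2 fold change 1.51, camera adjusted p = 8e-05 and 0.58 with an estimated correlation). The interleukin genes IL1A and IL1B rose by 5.94 ± 0.29 and 5.67 ± 0.3 and the growth factor gene CSF2 by 4.55 ± 0.23, while the chemokine gene CXCL1 changed by -6.55 ± 0.24. Mesenchymal genes rose in 10 and fell in 2 of 18 (median 1.13, adjusted p = 0.0055 and 0.58 with an estimated correlation), with VIM, an intermediate filament gene, at 3.40 ± 0.2 and LOX, a collagen cross-linking enzyme, at 3.28 ± 0.09, but N-cadherin (CDH2) at -3.79 ± 0.35. TGF-beta and YAP targets rose in 9 and fell in 1 of 20 (median 0.93, adjusted p = 0.0018) and cell adhesion genes in 8 and 4 of 23 (0.62, 0.012), among them the integrin gene ITGB3 at 6.20 ± 0.18. With an estimated correlation both had an adjusted p of 0.58. Antigen presentation genes rose in 5 and fell in 1 of 18 (0.64, 0.045 and 0.7 with an estimated correlation), among them HLA-DRA at 2.18 ± 0.12. Drug and redox defence genes fell in 17 of 22 and none was called higher (median -2.07, adjusted p = 5.5e-09 and 0.58 with an estimated correlation), with ALDH1A1, an aldehyde dehydrogenase, at -8.19 ± 0.16 and the efflux pump ABCC2 at -6.80 ± 0.16.

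The remaining lists did not pass in HCC1954 Lep with Par. The counts of called higher and lower members were 8 and 3 of 19 for the complement system, 5 and 1 of 15 for iron handling, 1 and 7 of 31 for interferon-stimulated genes, 6 and 5 of 28 for epithelial genes, 9 and 5 of 21 for collagens and matrix, and 6 and 2 of 23 for hypoxia and glycolysis. They were 1 and 3 of 26 for cholesterol and fatty acid synthesis, 5 and 4 of 25 for amino acid and endoplasmic reticulum stress, 3 and 0 of 19 for p53 targets, and 6 and 4 of 28 for semaphorins, ephrins and axon guidance. Brain metastasis genes counted 10 and 5 of 24, not independent evidence. The proliferation list had 0 calls of 26 in limma, edgeR and DESeq2, with 12 higher and 13 lower at an unadjusted p under 0.05. All HCC1954 list counts were the same adjusted over the list alone. C3, the central complement protein, had a mean of 11800 ± 300 in Lep and 5980 ± 337 in Par (0.98 ± 0.09, adjusted p = 1.3e-07), short of the fold threshold in limma and past it without Par replicate 3 (1.01). LCN2, an iron-siderophore carrier, rose by 2.23 ± 0.04 to 84000 ± 3130, and its receptor gene SLC22A17 by 3.88 ± 0.17 to 224 ± 17.3. ERBB2 rose by 1.33 ± 0.03 to 147000 ± 3260, but by 0.80 with quantile normalization, which ends the call. Host cell markers moved both ways. Among endothelial markers KDR (5.31), FLT1 (3.47) and CLDN5 (2.34) rose and PECAM1 (-3.18) and ESAM (-2.05) fell; among the others, OLIG2 (2.61), CRABP2 (1.34) and ALDH1A2 (1.15) rose, and CD14 (-1.08), FOXJ1 (-4.35) and FOLR1 (-1.99) fell.

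Between Int (n = 2) and Lep of HCC1954, adhesion, matrix and mesenchymal genes rose. SPARC, a matrix glycoprotein, rose by 4.30 ± 0.25, the receptor tyrosine kinase AXL by 3.63 ± 0.12, the gelatinase MMP2 by 3.04 ± 0.08 and CYP24A1, the vitamin D hydroxylase, from 90.4 ± 31 to 10100 ± 1680. C3 rose by 2.21 ± 0.1 from 2580 ± 597 and SERPING1, the C1 inhibitor, by 3.37 ± 0.32. IL1A rose by 6.41 ± 0.32. Mesenchymal genes rose in 12 of 18 (median 1.33, adjusted p = 4.1e-06), collagens and matrix in 15 of 21 (1.15, 4.1e-06), adhesion genes in 8 of 23 (0.73, 7.3e-07) and TGF-beta and YAP targets in 9 of 20 (0.84, 3.5e-05), with none called lower in these 4 lists. With an estimated correlation the adjusted p of these lists was 0.25 to 0.32. Corrected for length and GC, collagens and matrix counted 9 higher and 1 lower. NF-kB genes rose in 14 and fell in 1 (1.00, 0.0015), complement genes in 6 and 2 (0.53, 0.038) and brain metastasis genes, not independent evidence, in 8 and 1 (0.62, 0.0096). Their adjusted p with an estimated correlation was 0.41 to 0.43. Interferon-stimulated genes fell in 9 of 31 (median -0.51, adjusted p = 3e-04 and 0.44 with an estimated correlation), with IFIT1 at -2.65 ± 0.21 and RSAD2 at -2.44 ± 0.31, both antiviral effectors. Medians also fell for cholesterol and fatty acid synthesis (-0.29, 1 and 2 called higher and lower, 0.00017), amino acid and endoplasmic reticulum stress (-0.26, 1 and 2, 0.018), drug and redox defence (-0.23, 1 and 3, 0.034) and epithelial genes (-0.23, 4 and 4, 0.03). For these 4 lists the adjusted p was 0.25 to 0.46 with an estimated correlation, and drug and redox defence did not pass after length and GC correction (0.069). LCN2 (0.68 ± 0.04) and ERBB2 (-0.06 ± 0.03) were not called, and SLC22A17 rose by 2.99 ± 0.19. Of the host cell markers, CD14 (2.5), CD68 (1.14), CSF1R (2.82), COL1A1 (1.13), CRABP2 (1.09), ESAM (1.02), FLT1 (3.76), KDR (2.99), VWF (1.2), CD8A (1.07), OLIG2 (1.52) and FOLR1 (1.22) rose, and PECAM1 (-1.5) and FOXJ1 (-1.75) fell. Of 2357 called genes 1817 were higher, a share of 77.1% that was 58.0% with quantile normalization.

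At the Int stage of HCC1954 several of the genes lost in Lep were already low. GSTP1, LDHB and CBR1, a carbonyl reductase, had Int means of 7.36 ± 1.51, 9.2 ± 2.63 and 0 against 15300 ± 377, 17900 ± 407 and 1470 ± 60.4 in Par. LRRN1, a neuronal leucine-rich repeat protein, rose by 6.44 ± 0.33. Drug and redox defence genes fell in 15 of 22 (median -1.77, adjusted p = 1.4e-08), with ALDH1A1 at -8.27 ± 0.18 and ABCC2 at -5.30 ± 0.18; with an estimated correlation the adjusted p was 0.34. NF-kB genes rose in 9 and fell in 4 (0.78, 0.047), the chemokine gene CCL2 by 2.33 ± 0.11 and CXCL1 changing by -8.53 ± 0.27. Their adjusted p was 0.85 with an estimated correlation and 0.062 after length and GC correction. C3 changed by -1.23 ± 0.1, and by -0.99 without Int replicate 1, which ends the call. LCN2 rose by 1.55 ± 0.04 and ERBB2 by 1.39 ± 0.03, and SLC22A17 (0.90 ± 0.19) was not called in limma, but was without Int replicate 1 (1.16), after length and GC correction (1.07) and with quantile normalization (1.77). Of the lists that did not pass, brain metastasis, hypoxia and semaphorin genes had medians of 0.48, 0.25 and 0.32 but means of -0.36, -0.17 and -0.18. As for host cell markers, TBX18 (1.33), CLDN5 (1.61) and KDR (2.32) rose, and CD14 (-3.58), CD68 (-1.23), CSF1R (-3.62), ESAM (-3.07), PECAM1 (-1.68), SYT1 (-1.86), FOLR1 (-3.21), FOXJ1 (-2.60) and KCNJ13 (-1.13) fell. There were 1027 higher and 2279 lower genes, and the higher share of 31.1% was 54.4% with quantile normalization.

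HCC1954 BrM cells (n = 2) shared the loss of redox genes and had the highest ERBB2. ERBB2, the receptor tyrosine kinase HER2, rose by 2.77 ± 0.03 to 397000 ± 2710, and SORBS2, a cytoskeletal adaptor, by 7.44 ± 0.45. NLGN1, a synaptic adhesion protein, had a mean of 187 ± 5.02 and was listed at 0 in Par, and TUSC3 was listed at 0 in BrM. Drug and redox defence genes fell in 16 of 22 (median -2.25, adjusted p = 1.4e-08; adjusted p = 0.68 with an estimated correlation). Antigen presentation genes rose in 10 of 18 (1.04, 0.00012), with HLA-B at 1.89 ± 0.08, and NF-kB genes rose in 12 and fell in 2 (0.72, 0.026), with CXCL3 at 3.55 ± 0.13. For both the adjusted p was 0.92 with an estimated correlation. LCN2 rose by 2.48 ± 0.04 to 99700 ± 5840 and SLC22A17 by 2.49 ± 0.19, while C3 (0.57 ± 0.1) was not called. Among markers of host cells, ALDH1A2 (2.59), CRABP2 (1.42), TBX18 (1.24), CDH5 (2.69), CLDN5 (2.37), KDR (3.86), PECAM1 (2.20), VWF (3.30), OLIG2 (2.11) and RBFOX3 (1.21) rose, and CD14 (-2.71), CD68 (-1.47), CSF1R (-2.74), FOXC1 (-1.25), ESAM (-1.45), SYT1 (-1.46), FOXJ1 (-3.23) and KCNJ13 (-1.37) fell. There were 1498 higher and 2171 lower genes, a higher share of 40.8% that was 54.8% with quantile normalization.

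Set against BrM, HCC1954 Lep cells had higher SOX11 (9.57 ± 0.27), keratin 14 (KRT14, 8.95 ± 0.46) and IL1A (6.88 ± 0.32, and 6.29 without BrM replicate 1), and lower GATM, which makes the creatine precursor (-7.67 ± 0.31). Mesenchymal genes were higher in 13 of 18 (median 1.89, adjusted p = 0.00039 and 0.41 with an estimated correlation), with AXL at 4.66 ± 0.12 and VIM at 3.64 ± 0.23. TGF-beta and YAP targets were higher in 10 of 20 (0.97, 7.3e-07 and 0.35 with an estimated correlation), with TGFB1 at 2.81 ± 0.09. Collagens and matrix counted 11 higher and 1 lower (1.10, 5e-04), adhesion genes 11 and 2 (0.67, 0.0016) and semaphorins and ephrins 6 and 1 (0.40, 0.016), with EFNB1 at 3.24 ± 0.09. With an estimated correlation the adjusted p of these 3 lists was 0.35 to 0.41. Hypoxia genes counted 5 and 1 (0.28, 0.0097), with CA9, a carbonic anhydrase, at 4.64 ± 0.13, NF-kB genes 9 and 2 (0.49, 0.031) and brain metastasis genes, not independent evidence, 10 and 4 (0.81, 0.016), with an adjusted p of 0.53 to 0.55 with an estimated correlation. Cholesterol and fatty acid genes counted 1 and 3 (median -0.30, 0.014), with the synthase FASN at -1.54 ± 0.06. Antigen presentation had a median of -0.43 (0.002) with 0 called by limma, edgeR or DESeq2 and 2 higher and 14 lower at an unadjusted p under 0.05. With an estimated correlation the adjusted p of these 2 lists was 0.53. ERBB2 changed by -1.43 ± 0.03, SLC22A17 by 1.40 ± 0.19, C3 (0.41 ± 0.1) and LCN2 (-0.25 ± 0.04) not being called. Of the host cell markers, CD14 (1.63), CD68 (1.38), CSF1R (1.95), COL1A1 (1.38), FOXC1 (1.60), FLT1 (3.93), KDR (1.45) and CD8A (1.11) were higher, and ALDH1A2 (-1.44), CDH5 (-2.01), PECAM1 (-5.39), VWF (-2.48), RBFOX3 (-1.25), FOLR1 (-2.07) and FOXJ1 (-1.11) were lower. There were 1637 higher and 1018 lower genes, a higher share of 61.7% that was 52.3% with quantile normalization.

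**Figure D2:**
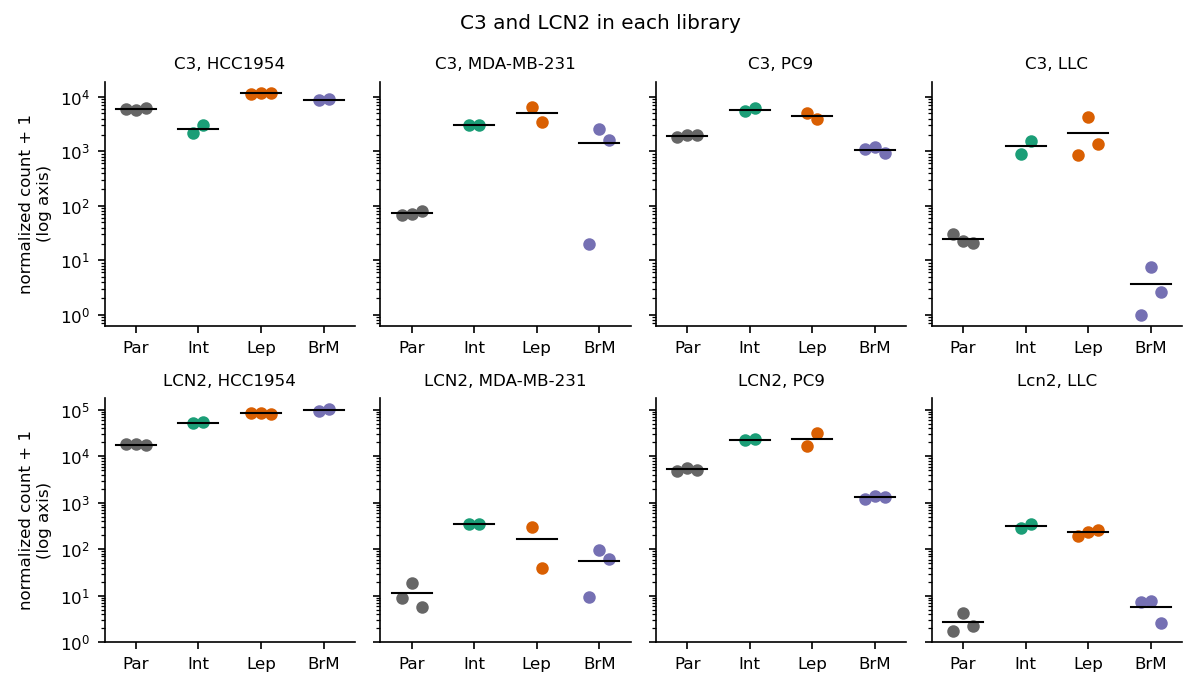
C3 and LCN2 in each library of the 4 models, as normalized counts plus 1 on a log axis; points are libraries and lines are group means.

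In MDA-MB-231, a breast line without hormone receptors or HER2, C3 had a mean of 4970 ± 2180 in Lep (n = 2) against 72.1 ± 7.91 in Par (n = 3), both Lep libraries lying above every Par library. The log2 fold change of 6.02 ± 1.66 did not pass in limma (adjusted p = 0.26), where the spread of C3 also comes from BrM, at 19.3, 2595 and 1621. It passed in DESeq2 (0.00043) and in a fit of the 2 groups only (0.0074), with 0.1 in edgeR and 0.1 to 0.54 over the libraries left out. LCN2 had means of 169 ± 185 and 10.3 ± 6.9 (3.43 ± 1.07, adjusted p = 0.32), and DESeq2 called it. It was 1.96 without Lep replicate 1 and 4.90 without Lep replicate 2. Among the called genes OLFML1, a secreted olfactomedin-like protein, changed by -5.56 ± 0.45 (5.42 ± 0.783 against 322 ± 140) and was called in every alternative. PTGFRN, a regulator of prostaglandin receptor binding, changed by -4.52 ± 0.39, and PTGES, which makes prostaglandin E2, rose by 2.46 ± 0.29 to 5310 ± 469. PTGFRN was not called with the 2 groups only, and PTGES neither there nor without Par replicate 2 (2.41) or Lep replicate 1 (2.37). The deposited Par libraries differed from each other: 3607 genes changed over 2-fold between replicates 1 and 3. In most libraries the deviation from the gene means followed transcript length, with Spearman correlations across genes of 0.55, -0.42 and -0.55 in Par 1, 2 and 3, 0.29 and 0.03 in Lep 1 and 2, 0.54 and 0.53 in Int, and -0.11, -0.56 and -0.53 in BrM.

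NF-kB target and cytokine genes lay higher as a list in MDA-MB-231 Lep than in Par (26 tested, median log2 fold change 1.92, camera adjusted p = 1.1e-14; adjusted p = 0.24 with an estimated correlation). limma called 0 of them over all genes and 12 adjusted over the list alone; 17 had an unadjusted p under 0.05, DESeq2 called 11 and edgeR 0. With an estimated correlation, the adjusted p of the lists that follow was 0.095 for epithelial genes, 0.21 for complement and p53, 0.24 for hypoxia, semaphorins and proliferation, 0.44 for antigen presentation and 0.5 for cholesterol. Epithelial genes had a median of 0.71 (0.00041; 4 adjusted over the list alone), the complement system 0.50 (0.02; 1), p53 targets 0.23 (0.0098; 1), hypoxia and glycolysis 0.17 (0.0062; 1), semaphorins 0.25 (0.0062; 1) and cholesterol and fatty acid synthesis 0.19 (0.027; 0). Proliferation (-0.28, 0.00016; 0) and antigen presentation (-0.46, 0.0062; 1 lower) had negative medians. Semaphorins did not pass after length and GC correction (0.061). limma called 0 genes of these lists over all genes. At an unadjusted p under 0.05 there were 4 complement, 6 epithelial, 4 p53, 5 hypoxia and 5 semaphorin genes higher, with 5 proliferation and 4 antigen presentation genes lower; DESeq2 called 1, 4, 1, 1, 1, 0 and 2 of them, and edgeR 1 p53 gene only. Brain metastasis genes, not independent evidence, had 1 member called lower (0.37, 0.0016; adjusted p = 0.23 with an estimated correlation) and 4 higher and 1 lower adjusted over the list alone. Adhesion genes had 1 called lower and did not pass (0.21). Iron handling (median 0.20), interferon-stimulated (0.23), mesenchymal (0.35), collagen (0.04), amino acid (0.35), TGF-beta (-0.13) and drug and redox (-0.04) genes did not pass either. limma and edgeR called 0 of each, while an unadjusted p under 0.05 held for 3, 6, 4, 2, 6, 1 and 0 higher genes and 1, 3, 0, 2, 3, 4 and 1 lower genes in that order. DESeq2 called 1, 3, 0, 2, 0, 0 and 0 higher and 0, 2, 0, 1, 0, 1 and 1 lower. No host marker was called. The split of the 10 called genes (3 higher, 7 lower of 15106) was not stable, with 47 higher and 34 lower after length and GC correction and 188 and 86 in DESeq2. They became 112 without Par replicate 1, 3 without Par replicate 2, 42 without Lep replicate 1 and 86 without Lep replicate 2.

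Between MDA-MB-231 Int (n = 2) and Lep, HTR1F, a serotonin receptor gene, was listed at 0 in Lep and had a mean of 197 ± 17.8 in Int. PTGFRN changed by -5.85 ± 0.43 from 790 ± 131. Both calls were absent with the 2 groups only, and PTGFRN was -5.26 without Lep replicate 1. Hypoxia and glycolysis genes lay lower (median -0.41, adjusted p = 3e-04; 0 higher and 1 lower called, 1 and 5 adjusted over the list alone), as did collagens and matrix (-0.74, 0.0017), adhesion genes (-0.64, 0.0031; 1 called lower), semaphorins (-0.44, 0.005), complement genes (-0.36, 0.039) and antigen presentation (-0.24, 0.034). Amino acid and endoplasmic reticulum stress genes lay higher (0.59, 0.0043). The adjusted p with an estimated correlation was 0.3 for the first 3 lists and for complement, 0.48 for semaphorins, 0.69 for antigen presentation and 0.59 for amino acid genes. Complement and semaphorins did not pass after length and GC correction (0.058 each), and brain metastasis genes, not independent evidence, did (0.042). Adjusted over the list alone, 4 collagen, 3 adhesion, 6 semaphorin, 2 complement and 4 antigen presentation genes were lower, and 3 amino acid genes higher. Among lists with 0 called by limma and edgeR, the genes at an unadjusted p under 0.05 numbered 6 lower for collagens, 8 for semaphorins, 5 for complement and 4 for antigen presentation, and 5 higher for amino acid genes; DESeq2 called 4, 5, 2, 3 and 3 of these. C3 (0.65 ± 1.82) and LCN2 (-1.66 ± 1.17, and -3.14 and -0.19 without Lep replicates 1 and 2) were not called. The 24 called genes (4 higher, 20 lower) were 50 with quantile normalization, where the higher share went from 16.7% to 30%, and DESeq2 called 218 higher and 252 lower. They numbered 2 without Int replicate 1, 2 without Int replicate 2, 369 without Lep replicate 1 and 47 without Lep replicate 2.

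In MDA-MB-231 Int cells VEGFA, the endothelial growth factor, rose by 2.52 ± 0.22 to 28100 ± 27.1, the glycolytic regulator PFKFB4 by 2.00 ± 0.18, and the integrin gene ITGA1 by 3.21 ± 0.37. Without Int replicate 2 the calls of PFKFB4 (1.93) and ITGA1 (2.79) ended. LCN2 rose by 5.10 ± 1.07 to 343 ± 3.92, while C3 (5.37 ± 1.66, mean 3020 ± 56.3) had an adjusted p of 0.063 in limma. C3 was called by edgeR (5.43, adjusted p = 0.03), DESeq2 (5.39, 0.00062) and the fit of the 2 groups only (0.0037). NF-kB genes counted 12 higher and 0 lower of 26 (median 2.54, adjusted p = 3.5e-08 and 0.25 with an estimated correlation). Hypoxia genes counted 11 higher and 1 lower of 24 (median 0.80, adjusted p = 1e-04 and 0.23 with an estimated correlation), semaphorins and ephrins 7 higher and 0 lower of 28 (median 0.73, adjusted p = 0.00087 and 0.23 with an estimated correlation), complement genes 4 higher and 0 lower of 18 (median 0.84, adjusted p = 0.0038 and 0.23 with an estimated correlation) and adhesion genes 6 higher and 0 lower of 24 (median 0.46, adjusted p = 0.0098 and 0.23 with an estimated correlation). Collagens and matrix counted 5 and 1 (0.0098), epithelial genes 5 and 1 (0.036), and proliferation 0 and 1 (median -0.39, 0.0014); the adjusted p with an estimated correlation was 0.23, 0.23 and 0.25. After length and GC correction collagens (0.093, 3 higher and 2 lower) and adhesion (0.078) did not pass, while complement and epithelial genes counted 7 and 8 higher. Brain metastasis genes, not independent evidence, counted 6 higher and 1 lower of 24 (median 0.76, adjusted p = 0.0015 and 0.23 with an estimated correlation). Adjusted over the list alone the higher counts were 20 for NF-kB, 8 for complement, 11 for semaphorins, 8 for adhesion, 7 for collagens, 9 for epithelial and 9 for brain metastasis genes. Macrophage markers passed with 1 called (median 1.39, 0.036; adjusted p = 0.25 with an estimated correlation). Of host markers, CSF1R (1.99), PDGFRB (2.59), CDH5 (3.37), PECAM1 (4.16) and AQP1 (2.04) rose, and SNAP25 (-1.91) fell. The higher share of 62.3% was 53.3% with quantile normalization, and DESeq2 called more lower (1166) than higher (1004). After length and GC correction ITGA1 was 2.54 and LCN2 5.79. Every call ended without Int replicate 2: the 1049 called genes (654 higher, 395 lower) were 0 without Int replicate 2, 10 without Int replicate 1, 3845 without Par replicate 1, 132 without Par replicate 2 and 408 without Par replicate 3. LCN2 was not called without Par replicate 2 (5.56), Par replicate 3 (4.71), Int replicate 1 (5.11) or Int replicate 2 (5.09), and C3 was called without Par replicate 1 (5.31).

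In MDA-MB-231 BrM (n = 3) RFPL4A, a germline ubiquitin ligase relative, rose by 7.88 ± 0.62 to 533 ± 94.4 and was called in every alternative; its close paralogs make the gene assignment uncertain. COX7B2, a cytochrome oxidase subunit, was listed at 0 in BrM. C3 (2.60 ± 1.48, mean 1410 ± 1300, adjusted p = 0.43) and LCN2 (1.93 ± 0.96) were not called by limma. DESeq2 called C3 (4.30, adjusted p = 0.0081) and edgeR did not (0.13), and limma called it at 4.82 without BrM replicate 1. It was 1.32 without BrM replicate 2 and 1.66 without BrM replicate 3, and LCN2 was 2.93 without BrM replicate 1 and 1.27 without BrM replicate 2. NF-kB genes lay higher (median 1.14, adjusted p = 1.7e-05; 0.62 with an estimated correlation), as did cholesterol and fatty acid genes (0.54, 1.2e-05; 0.6) and epithelial genes (0.43, 0.0041; 0.23). Proliferation (-0.19, 0.0041; 0.6) and TGF-beta and YAP targets (-0.41, 0.0041; 0.24) lay lower. limma and edgeR called 0 genes in these 5 lists, with 1 epithelial gene adjusted over the list alone. At an unadjusted p under 0.05, 10 NF-kB, 10 cholesterol and 7 epithelial genes were higher and 5 proliferation and 6 TGF-beta genes lower; DESeq2 called 9, 0, 3, 0 and 1. Blocking by replicate number took hypoxia genes from 0.078 to 0.046 and amino acid and endoplasmic reticulum stress genes from 0.052 to 0.026, against 0.62 and 0.66 with an estimated correlation. Drug and redox defence passed only after length and GC correction (0.037). Of host markers, CRABP2 (1.99) rose. DESeq2 called 248 higher and 223 lower. The 68 called genes (52 higher, 16 lower) numbered 20, 4 and 422 (137 higher, 285 lower) without Par replicates 1, 2 and 3, and 45, 3 and 2 without BrM replicates 1, 2 and 3.

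Against BrM, MDA-MB-231 Lep cells had lower ITM2A, a membrane protein of differentiating cells (-6.48 ± 0.57, 6.02 ± 6.4 against 493 ± 150), and lower OLFML1 (-5.48 ± 0.45), both called in every alternative. ITM2A was -7.58 without Lep replicate 1 and -5.37 without Lep replicate 2. C5orf46, a small secreted protein, was higher (4.04 ± 0.45) except without BrM replicate 3 (4.07, not called). C3 (3.42 ± 1.66, adjusted p = 0.26) and LCN2 (1.5 ± 1.07) were not called. C3 was 1.2, 4.70 and 4.36 without BrM replicates 1, 2 and 3. Brain metastasis genes, not independent evidence, counted 2 higher and 0 lower of 24 (median 0.66, adjusted p = 0.0036 and 0.58 with an estimated correlation), and 5 higher and 1 lower adjusted over the list alone. NF-kB genes lay higher (median 0.87, 0.033) and antigen presentation lower (-0.45, 0.033), each with an adjusted p of 0.7 with an estimated correlation. Antigen presentation did not pass after length and GC correction (0.16). limma and edgeR called 0 in both, DESeq2 2 and 3; an unadjusted p under 0.05 held for 5 higher and 5 lower genes respectively. Of host markers, CRABP2 (-1.53) was lower. The higher share of 41.6% was 33.1% with quantile normalization, while 176 were higher and 156 lower after length and GC correction and 465 and 275 in DESeq2. The 125 called genes (52 higher, 73 lower) numbered 58 and 361 without Lep replicates 1 and 2, and 20, 26 and 6 without BrM replicates 1, 2 and 3.

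In PC9, the lung line whose labels name raised EGFR, EGFR itself fell in Lep (n = 2) to 1730 ± 284 from 9440 ± 304 in Par (n = 3), a log2 fold change of -2.46 ± 0.11. CASP14, a caspase of keratinizing cells, rose by 6.39 ± 0.46, the imprinted transcript H19 by 4.72 ± 0.16 and TRIM31, a ubiquitin ligase, by 4.69 ± 0.26. LCP1, an actin bundler of blood cells, changed by -5.31 ± 0.07. LCN2 rose by 2.13 ± 0.18 to 24000 ± 10300, C3 by 1.19 ± 0.11 to 4470 ± 783 from 1940 ± 80 (adjusted p = 1.6e-06), and TFRC, the transferrin receptor, changed by -2.32 ± 0.08. IFI27, an interferon-induced mitochondrial protein, rose by 5.57 ± 0.6 (4.96 without Par replicate 2), and BCAT1, a branched-chain aminotransferase, changed by -4.68 ± 1.07 but by -7.64 without Lep replicate 1 and -1.73 without Lep replicate 2. There were 962 higher and 1229 lower genes of 14475 tested. In this model the deviation of a library from the gene means also followed transcript length, with correlations of 0.38, 0.40 and 0.41 in Par, -0.55 and -0.50 in Int, -0.53 and -0.43 in Lep and 0.49, 0.45 and 0.33 in BrM. After correction for length and GC, 1647 genes were called in Lep with Par, 1304 of them the same as before. EGFR was then -1.85, LCN2 1.53 and BCAT1 -4.04.

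**Figure D3:**
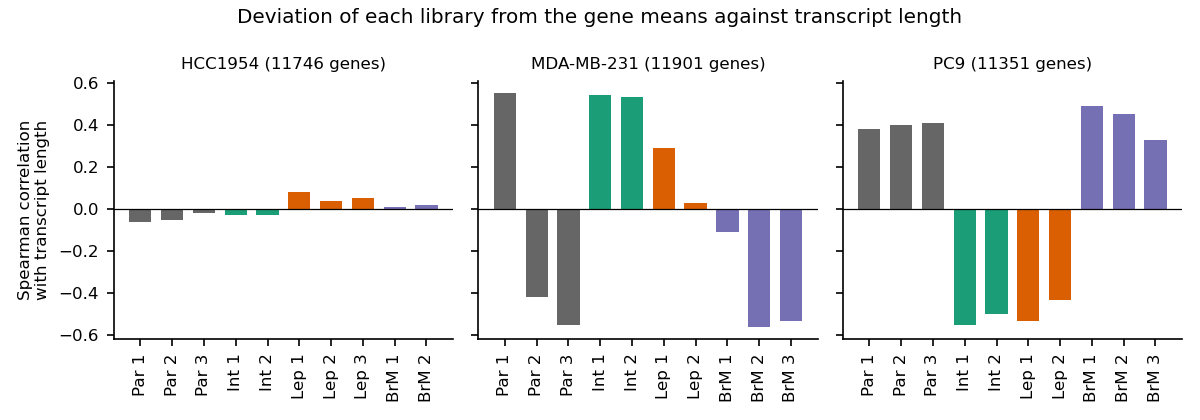
Correlation across genes between transcript length and the deviation of each human library from its gene means.

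In PC9 Lep, NF-kB genes counted 9 higher and 0 lower of 23 (median 0.86, adjusted p = 0.0014 and 0.35 with an estimated correlation), with the serum amyloid gene SAA1 at 2.90 ± 0.16 and TNF at 2.19 ± 0.29. Interferon-stimulated genes counted 13 higher and 0 lower of 28 (median 0.95, adjusted p = 0.0025 and 0.32 with an estimated correlation), with BST2, which tethers virions, at 1.85 ± 0.07. Epithelial genes counted 6 higher and 2 lower of 27 (median 0.37, adjusted p = 0.0025 and 0.35 with an estimated correlation), with KRT17 at 4.17 ± 0.44 (3.34 without Lep replicate 1, 4.99 without Lep replicate 2), and antigen presentation 4 higher and 0 lower of 16 (median 0.48, adjusted p = 0.011 and 0.35 with an estimated correlation), with CD74 at 2.74 ± 0.44. Corrected for length and GC, antigen presentation did not pass (0.11, 1 higher), epithelial genes counted 2 and 0 (0.018) and drug and redox defence did (0.0019, median -0.36). Without that correction drug and redox defence counted 1 and 6 of 22. The other lists did not pass: complement 5 and 0 of 15, iron handling 2 and 3 of 13, mesenchymal 1 and 0 of 15, collagens and matrix 1 and 5 of 20, proliferation 0 and 1 of 26, hypoxia 2 and 0 of 24 and cholesterol 3 and 1 of 26. The same held for amino acid stress 1 and 1 of 25, TGF-beta and YAP targets 0 and 1 of 20 (median 0.07, mean -0.12), p53 targets 3 and 2 of 19 (median 0.07, mean -0.03), adhesion 2 and 5 of 22 and semaphorins 2 and 2 of 28. Brain metastasis genes counted 5 and 1 of 20, not independent evidence. Counts were the same adjusted over the list alone. Markers of host cells that rose were ITGAM (3.87), CD14 (2.07), SLC6A13 (2.38), PDGFRB (2.20), PECAM1 (2.44), CDH5 (1.29) and FOLR1 (2.55); SNAP25 changed by -2.30 and no lymphocyte marker was called. The call of INSIG1, a brake on sterol synthesis (1.12 ± 0.44), ended without Lep replicate 2 (-0.07) or any Par replicate (1.17, 1.13 and 1.06), and it was 2.31 without Lep replicate 1.

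PC9 Lep and Int (n = 2) cells were close, with 33 higher and 55 lower genes. SPRR1B, a cornified envelope protein, was higher (2.33 ± 0.23, 913 ± 243 against 182 ± 51.8), as were TRIM31 (2.55 ± 0.29) and IFI27 (4.26 ± 0.66), while LCP1 (-3.91 ± 0.08) and the fatty acid desaturase FADS2 (-3.33 ± 0.3) were lower. IFI27 was not called without Int replicate 2 (4.06), and FADS2 was -2.62 without Lep replicate 1 and -4.03 without Lep replicate 2. C3 (-0.39 ± 0.12), LCN2 (0.01 ± 0.2) and EGFR (-0.01 ± 0.12) were not called. Cholesterol and fatty acid genes counted 0 higher and 4 lower of 26 (median -0.77, adjusted p = 2.5e-20 and 0.51 with an estimated correlation), and 6 lower adjusted over the list alone. Hypoxia genes counted 0 higher and 1 lower of 24 (median -0.21, adjusted p = 6.5e-07 and 0.51 with an estimated correlation) and semaphorins 2 higher and 0 lower of 28 (median 0.11, adjusted p = 0.032 and 0.55 with an estimated correlation), with SEMA5A at 1.73 ± 0.16 and 2 higher and 2 lower adjusted over the list alone. Semaphorins did not pass after length and GC correction (0.061). Mesenchymal (median -0.30, 0.0052; 0.51 with an estimated correlation), NF-kB (-0.15, 0.014; 0.58) and antigen presentation genes (-0.17, 0.015; 0.58) lay lower with 0 called by limma, edgeR and DESeq2 and 5, 5 and 4 lower at an unadjusted p under 0.05. edgeR called 68 higher and 58 lower, and DESeq2 49 and 48. The 88 called genes numbered 42 and 26 without Int replicates 1 and 2 and 371 and 210 without Lep replicates 1 and 2.

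PC9 Int cells had already lost EGFR (-2.45 ± 0.11) and gained LCN2 (2.13 ± 0.18) and C3 (1.58 ± 0.11, mean 5830 ± 548) relative to Par. SCD, which desaturates fatty acids, rose by 4.64 ± 0.61 to 44400 ± 2720, CXCL17, a mucosal chemokine, by 5.05 ± 0.51, and TLR4, the endotoxin receptor, changed by -5.55 ± 0.19. Cholesterol and fatty acid genes counted 13 higher and 0 lower of 26 (median 0.91, adjusted p = 7.4e-05 and 0.49 with an estimated correlation) and NF-kB genes 14 higher and 0 lower of 23 (median 1.14, adjusted p = 2.9e-05 and 0.41 with an estimated correlation), with CCL20 at 2.60 ± 0.42. Interferon-stimulated genes counted 8 higher and 0 lower of 28 (median 0.66, adjusted p = 0.0054 and 0.41 with an estimated correlation), antigen presentation 5 higher and 0 lower of 16 (median 0.67, adjusted p = 0.0012 and 0.41 with an estimated correlation), epithelial genes 5 higher and 1 lower of 27 (median 0.34, adjusted p = 0.0054 and 0.41 with an estimated correlation) and hypoxia genes 5 higher and 0 lower of 24 (median 0.43, adjusted p = 0.015 and 0.49 with an estimated correlation). As for host cell markers, CD14 (1.89), ITGAM (2.88), ALDH1A2 (1.97), CRABP2 (1.05), SLC6A13 (1.89), CDH5 (1.27), PECAM1 (2.18), AQP1 (1.02) and FOLR1 (2.83) rose, and CD8A (-1.19) and SNAP25 (-2.62) fell. There were 903 higher and 1116 lower genes, and 1170 of these 2019 were also called after length and GC correction, which took the complement list (6 higher) past its threshold (0.038), along with drug and redox defence (0.009) and brain metastasis genes (0.034, not independent evidence). With it EGFR was -1.86, LCN2 1.55 and TLR4 -4.87. It left 2 higher genes each in the antigen presentation (0.0087) and epithelial lists (0.034).

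PC9 BrM cells (n = 3) raised mesenchymal and matrix genes. Fibronectin (FN1) rose by 5.38 ± 0.25 from 3800 ± 212 to 159000 ± 4400 and vimentin (VIM) by 5.25 ± 0.29. FGFR2, a growth factor receptor, had a mean of 118 ± 19 and was listed at 0 in Par. S100A8, an inflammatory calcium-binding protein, changed by -7.46 ± 0.38. Drug and redox defence counted 1 higher and 11 lower of 22 (median -0.96, adjusted p = 1.8e-12 and 0.017 with an estimated correlation), with ALDH1A1 at -4.80 ± 0.28; this is the only list call of the series that holds in that setting. TGF-beta and YAP targets counted 11 higher and 2 lower of 20 (median 1.26, adjusted p = 5.9e-08 and 0.18 with an estimated correlation), mesenchymal genes 7 higher and 0 lower of 15 (median 0.99, adjusted p = 1.6e-06 and 0.15 with an estimated correlation), collagens and matrix 6 higher and 1 lower of 20 (median 0.74, adjusted p = 4e-04 and 0.18 with an estimated correlation), adhesion genes 6 higher and 1 lower of 22 (median 0.43, adjusted p = 0.00025 and 0.18 with an estimated correlation) and hypoxia genes 7 higher and 0 lower of 24 (median 0.49, adjusted p = 8.1e-08 and 0.18 with an estimated correlation). Cholesterol genes counted 5 higher and 0 lower of 26 (median 0.71, adjusted p = 2.2e-06 and 0.38 with an estimated correlation), NF-kB genes 0 higher and 10 lower of 23 (median -0.39, adjusted p = 0.00025 and 0.2 with an estimated correlation), iron handling 0 higher and 3 lower of 13 (median -0.24, adjusted p = 0.0069 and 0.15 with an estimated correlation) and epithelial genes 1 higher and 1 lower of 27 (median 0.17, adjusted p = 0.0024 and 0.18 with an estimated correlation). Proliferation lay lower (median -0.27, 1.1e-06; adjusted p = 0.18 with an estimated correlation) with 0 called by limma, edgeR and DESeq2 and 23 lower at an unadjusted p under 0.05. LCN2 changed by -1.98 ± 0.16, and C3 (-0.86 ± 0.1) and EGFR (0.48 ± 0.1) were not called. Of host markers, CSF1R (2.13) rose, and ALDH1A2 (-1.75), PECAM1 (-5.23), SLC1A3 (-1.63) and FOLR1 (-1.51) fell. There were 669 higher and 449 lower genes.

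Against BrM, PC9 Lep cells had higher S100A8 (11.12 ± 0.42, 18000 ± 1630 against 8.57 ± 6.57), the mucin MUC5B (8.08 ± 0.12) and SAA1 (7.72 ± 0.16), and lower levels of the integrin gene ITGB6 (-3.16 ± 0.13) and EGFR (-2.93 ± 0.11). C3 was higher by 2.05 ± 0.11, LCN2 by 4.11 ± 0.18 and factor B (CFB) by 2.46 ± 0.08. NF-kB genes counted 16 higher and 0 lower of 23 (median 1.19, adjusted p = 4.9e-06 and 0.2 with an estimated correlation), interferon-stimulated genes 12 higher and 0 lower of 28 (median 0.82, adjusted p = 0.0044 and 0.2 with an estimated correlation), complement genes 7 higher and 0 lower of 15 (median 0.97, adjusted p = 0.019 and 0.2 with an estimated correlation) and drug and redox defence 6 higher and 1 lower of 22 (median 0.62, adjusted p = 0.0053 and 0.2 with an estimated correlation). Antigen presentation counted 4 higher and 0 lower of 16 (median 0.44, adjusted p = 0.0053 and 0.28 with an estimated correlation) and did not pass after length and GC correction (0.084). TGF-beta and YAP targets counted 2 higher and 12 lower of 20 (median -1.12, adjusted p = 0.00016 and 0.31 with an estimated correlation), mesenchymal genes 0 higher and 10 lower of 15 (median -1.60, adjusted p = 0.0019 and 0.2 with an estimated correlation), collagens 1 higher and 9 lower of 20 (median -0.98, adjusted p = 0.0019 and 0.2 with an estimated correlation), adhesion genes 1 higher and 9 lower of 22 (median -0.71, adjusted p = 0.0023 and 0.23 with an estimated correlation) and hypoxia genes 0 higher and 4 lower of 24 (median -0.46, adjusted p = 0.0072 and 0.45 with an estimated correlation). After this correction cholesterol genes passed (0.041), and adhesion counted 2 higher and 4 lower and hypoxia 2 lower. S100A8 was 10.42, MUC5B 8.68, SAA1 7.06, LCN2 3.42 and EGFR -2.28. Of the host cell markers, CD14 (2.94), ITGAM (3.48), ALDH1A2 (3.53), CRABP2 (1.21), PDGFRB (1.62), SLC6A13 (3.11), PECAM1 (7.67), AQP1 (1.64) and FOLR1 (4.06) were higher, and CSF1R (-1.49), MBP (-1.18) and SNAP25 (-2.99) were lower. There were 1134 higher and 1562 lower genes, 1737 of them also called after that correction.

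**Figure D4:**
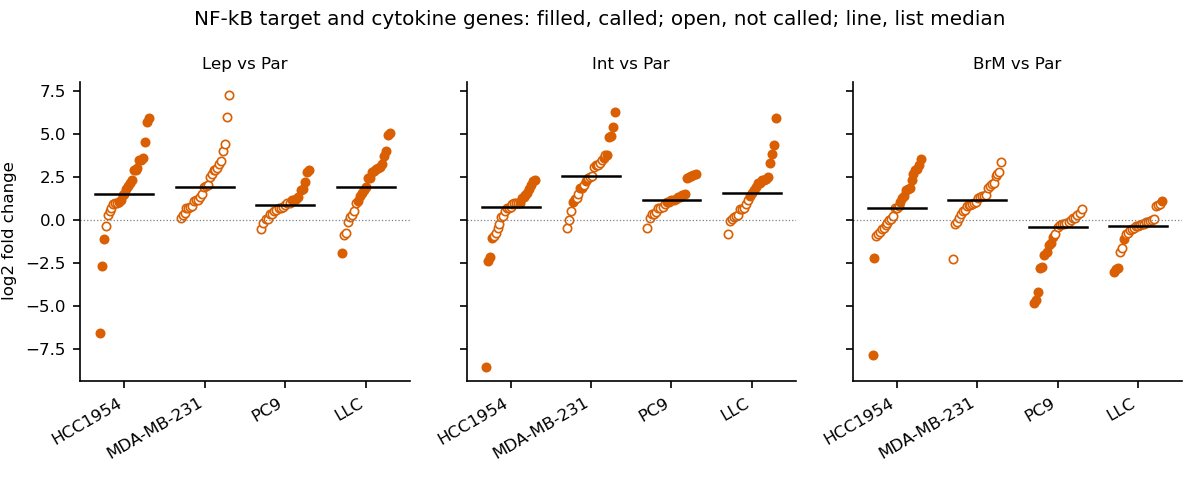
Log2 fold changes of the NF-kB target and cytokine genes in Lep with Par for each model, with the list median.

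In the mouse lung carcinoma LLC, C3 rose in Lep (n = 3) to 2150 ± 1820 from 23.8 ± 4.75 in Par (n = 3), a log2 fold change of 6.12 ± 0.67 (adjusted p = 2.4e-05; 5.46 without Lep replicate 2). Lcn2 rose by 6.50 ± 0.45 to 230 ± 33.8, while its receptor gene Slc22a17 changed by -3.49 ± 0.6 (-2.73 without Lep replicate 2, -4.42 without Lep replicate 3). Alpha-fetoprotein (Afp) rose by 6.36 ± 0.34 and the chemokine gene Ccl20 by 4.96 ± 0.54. The proteoglycan gene Bgn changed by -8.58 ± 0.42, and Hoxb3, Hoxb2 and H19 were listed at 0 in every Lep library. NF-kB genes counted 17 higher and 1 lower of 25 (median 1.89, adjusted p = 1.1e-06 and 0.39 with an estimated correlation), proliferation genes 7 higher and 0 lower of 26 (median 0.81, adjusted p = 2e-08 and 0.39 with an estimated correlation), with Birc5 at 1.41 ± 0.19, and cholesterol and fatty acid genes 0 higher and 13 lower of 27 (median -1, adjusted p = 1.1e-06 and 0.39 with an estimated correlation), with Fads2 at -3.33 ± 0.26. Amino acid and endoplasmic reticulum stress genes counted 0 higher and 8 lower of 25 (median -0.78, adjusted p = 3e-04 and 0.6 with an estimated correlation) and p53 targets 1 higher and 5 lower of 17 (median -0.74, adjusted p = 0.011 and 0.39 with an estimated correlation), with Cdkn1a at -1.82 ± 0.2. The other lists did not pass: complement 2 and 7 of 14, iron handling 2 and 2 of 14, interferon-stimulated 3 and 3 of 22, antigen presentation 1 and 1 of 14, epithelial 6 and 2 of 16, mesenchymal 5 and 5 of 20, collagens 4 and 10 of 23 and hypoxia 1 and 6 of 22. The same held for TGF-beta and YAP targets 7 and 0 of 17, drug and redox defence 1 and 1 of 19, adhesion 2 and 6 of 21, semaphorins 3 and 5 of 25 and brain metastasis genes 5 and 1 of 17, the last not independent evidence. Adjusted over the list alone, the counts were 6 and 4 for epithelial genes, 6 and 10 for collagens, 8 and 0 for TGF-beta targets, 2 and 7 for adhesion, and 4 and 5 for semaphorins. Of host markers, Mrc1 (3.29), Cx3cr1 (1.48), Pdgfrb (2.20) and Pecam1 (1.60) rose, and Lum (-7.06), Dcn (-2.85), Col3a1 (-2.66) and Enpp2 (-3.93) fell; no lymphocyte marker was called. There were 1079 higher and 1655 lower genes of 13494, a higher share of 39.5% that was 49.1% with quantile normalization.

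Compared with Int (n = 2), LLC Lep cells raised cell cycle genes and lowered hypoxia and p53 genes. Thymidylate synthase (Tyms) rose by 2.16 ± 0.23 and cyclin B1 (Ccnb1) by 1.54 ± 0.14. Adrenomedullin (Adm) changed by -3.69 ± 0.38, the cell cycle inhibitor Cdkn1a by -2.97 ± 0.22, the chaperone Hspa5 by -2.37 ± 0.25 and the protease Adam19 by -8.30 ± 0.39. Proliferation counted 10 higher and 0 lower of 26 (median 0.91, adjusted p = 4.3e-10 and 0.43 with an estimated correlation), hypoxia 0 higher and 15 lower of 22 (median -1.36, adjusted p = 6.8e-06 and 0.43 with an estimated correlation), p53 targets 0 higher and 9 lower of 17 (median -1.09, adjusted p = 1.5e-06 and 0.21 with an estimated correlation) and cholesterol genes 0 higher and 14 lower of 27 (median -1.03, adjusted p = 1.9e-05 and 0.43 with an estimated correlation). Adhesion counted 0 higher and 8 lower of 21 (median -0.84, adjusted p = 0.0069 and 0.46 with an estimated correlation), amino acid stress 0 higher and 8 lower of 25 (median -0.68, adjusted p = 0.0083 and 0.81 with an estimated correlation) and drug and redox defence 1 higher and 8 lower of 19 (median -0.51, adjusted p = 0.027 and 0.58 with an estimated correlation). Collagens did not pass, with a median of 0.45 and a mean of -0.31. C3 (0.53 ± 0.74, and -0.13 without Lep replicate 2) and Lcn2 (-0.47 ± 0.5) were not called. Slc22a17 changed by -4.01 ± 0.67, or -3.25 without Lep replicate 2 and -4.94 without Lep replicate 3. As for host cell markers, Lyz2 (3.77), Mrc1 (2.00), Col1a2 (3.37), Pdgfrb (3.40), Zic1 (2.23) and Slc1a3 (2.48) rose, and Cd68 (-4.86), Cx3cr1 (-2.35), Col3a1 (-1.15), Crabp2 (-1.80), Dcn (-1.97), Lum (-8.15, -7.09 without Int replicate 1, -9.21 without Int replicate 2), Pdgfra (-1.21), Mbp (-1.02) and Aqp1 (-2.82) fell. There were 1143 higher and 1893 lower genes; the higher share of 37.6% was 48.5% with quantile normalization.

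LLC Int cells gained C3 (5.59 ± 0.74, mean 1230 ± 467) and Lcn2 (6.97 ± 0.5, mean 317 ± 37.7) relative to Par. Nos2, the inducible nitric oxide synthase, rose by 8.23 ± 0.72, the quinone reductase Nqo1 by 2.55 ± 0.22 and the death receptor Fas by 3.76 ± 0.4. NF-kB genes counted 14 higher and 0 lower of 25 (median 1.59, adjusted p = 3.8e-09 and 0.17 with an estimated correlation), hypoxia 8 higher and 0 lower of 22 (median 0.79, adjusted p = 9.9e-07 and 0.17 with an estimated correlation), drug and redox defence 8 higher and 0 lower of 19 (median 0.63, adjusted p = 2.2e-05 and 0.17 with an estimated correlation) and p53 targets 4 higher and 0 lower of 17 (median 0.61, adjusted p = 2e-04 and 0.17 with an estimated correlation). TGF-beta and YAP targets counted 4 higher and 0 lower of 17 (median 0.45, adjusted p = 0.013 and 0.31 with an estimated correlation), adhesion 5 higher and 0 lower of 21 (median 0.27, adjusted p = 0.025 and 0.33 with an estimated correlation), antigen presentation 2 higher and 0 lower of 14 (median 0.50, adjusted p = 0.0073 and 0.31 with an estimated correlation) and brain metastasis genes, not independent evidence, 5 higher and 0 lower of 17 (median 0.59, adjusted p = 0.0064 and 0.26 with an estimated correlation). Adjusted over the list alone the counts were 5 and 1 for adhesion and 6 and 1 for brain metastasis genes. Fibroblast markers counted 1 higher and 4 lower of 11 (median -1.2, adjusted p = 0.038 and 0.17 with an estimated correlation). Among markers of host cells, Cd68 (4.59), Cx3cr1 (3.83), Crabp2 (2.18), Flt1 (1.52), Tubb3 (1.84), Aqp1 (2.25) and Kcnj13 (1.78) rose, and Lyz2 (-2.74), Col1a1 (-2.58), Col1a2 (-2.11), Col3a1 (-1.51), Foxc1 (-1.2) and Enpp2 (-3.14) fell. There were 863 higher and 685 lower genes.

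LLC BrM cells (n = 3) lost complement and antigen presentation genes. The complement protease C1s changed by -4.77 ± 0.23 and the class I gene H2-K1 by -2.95 ± 0.24; C3 had means of 2.73 ± 3.41 and 23.8 ± 4.75 (-3.17 ± 0.67; -2.45 without BrM replicate 1, -3.91 without BrM replicate 2). The smooth muscle actin gene Acta2 rose by 4.88 ± 0.39, and the imprinted gene Peg3 changed by -9.82 ± 0.43. Proliferation counted 10 higher and 0 lower of 26 (median 0.93, adjusted p = 2.9e-10 and 0.36 with an estimated correlation), antigen presentation 1 higher and 7 lower of 14 (median -1.34, adjusted p = 0.014 and 0.47 with an estimated correlation), interferon-stimulated genes 1 higher and 10 lower of 22 (median -0.88, adjusted p = 0.016 and 0.23 with an estimated correlation) and complement 0 higher and 7 lower of 14 (median -1.02, adjusted p = 0.025 and 0.23 with an estimated correlation). Collagens counted 2 higher and 12 lower of 23 (median -1.22, adjusted p = 0.025 and 0.63 with an estimated correlation), semaphorins 2 higher and 8 lower of 25 (median -0.51, adjusted p = 0.03 and 0.63 with an estimated correlation), amino acid stress 2 higher and 10 lower of 25 (median -0.49, adjusted p = 0.03 and 0.77 with an estimated correlation) and fibroblast markers 0 higher and 4 lower of 11 (median -0.70, adjusted p = 0.038 and 0.26 with an estimated correlation). Lcn2 (1.06 ± 0.45) and Slc22a17 (-0.38 ± 0.6) were not called; Lcn2 was called without Par replicate 2 (1.45) or BrM replicate 3 (1.56). Of host markers, Cx3cr1 (2.20), Slc1a3 (1.52) and Tubb3 (1.62) rose, and Lyz2 (-4.54), Col1a1 (-2.03), Dcn (-4.22), Pdgfra (-1.70), Tbx18 (mean 91.3 to 0), Vwf (-2.64), Mbp (-1.33), Syt1 (-3.75), Aqp1 (-1.55) and Enpp2 (-5.73) fell. There were 1099 higher and 2037 lower genes, a higher share of 35% that was 50.5% with quantile normalization.

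Against BrM, LLC Lep cells had higher C3, with means of 2150 ± 1820 and 2.73 ± 3.41, and higher Lcn2 (5.44 ± 0.45). The fold of C3 depends on the added constant, being 9.29 and then 8.64, 8.57 and 10.03 without Lep replicate 2, BrM replicate 1 and BrM replicate 2. Nlrc5, which drives class I genes, was higher by 3.90 ± 0.25 and Ccl20 by 5.50 ± 0.54, while Slc22a17 (-3.11 ± 0.6; -2.35 without Lep replicate 2, -4.04 without Lep replicate 3) and the growth factor adaptor Grb10 (-8.56 ± 0.33) were lower. NF-kB genes counted 16 higher and 0 lower of 25 (median 2.23, adjusted p = 1.2e-08 and 0.27 with an estimated correlation), antigen presentation 6 higher and 0 lower of 14 (median 0.56, adjusted p = 0.0041 and 0.37 with an estimated correlation), interferon-stimulated genes 11 higher and 2 lower of 22 (median 1.08, adjusted p = 0.024 and 0.27 with an estimated correlation) and cholesterol genes 0 higher and 13 lower of 27 (median -0.95, adjusted p = 8.7e-08 and 0.27 with an estimated correlation). TGF-beta and YAP targets counted 6 higher and 0 lower of 17 (median 0.63, adjusted p = 0.041 and 0.47 with an estimated correlation) and brain metastasis genes, not independent evidence, 4 higher and 0 lower of 17 (median 0.73, adjusted p = 0.018 and 0.37 with an estimated correlation). Of host markers, Lyz2 (5.57), Mrc1 (3.91), Dcn (1.37), Pdgfrb (3.12), Tbx18 (means 94.6 and 0), Flt1 (1.12), Vwf (2.28), Syt1 (3.88) and Enpp2 (1.80) were higher, and Col3a1 (-1.96) and Lum (-6.65) were lower. There were 1502 higher and 925 lower genes, a higher share of 61.9% that was 53% with quantile normalization.

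Across models, LCN2 rose in Lep with Par by 2.23 in HCC1954, 2.13 in PC9 and 6.50 in LLC. The LLC fold depends on the added constant (1 to 5 reads per Par library). ANGPTL4, a lipase inhibitor, CCL20 and NFKBIA, the NF-kB inhibitor, also rose in these 3. The peptidase gene MME (-3.24, -4.94 and -3.77) and osteopontin (SPP1, -8.11, -3.84 and -2.38) fell. In all, 54 of 13871 genes were called one way in at least 3 of 4 models, 22 higher and 32 lower, against a chance mean of 23.6 and a maximum of 43 over 10000 permutations (permutation p = 1e-04, the smallest possible). limma called 0 of 13377 genes in all 3 human models and edgeR 0, with 34 at an unadjusted p under 0.05 and 13 called by DESeq2. In all 4 models limma and edgeR called 0 of 9811, with 9 at an unadjusted p under 0.05 and 4 by DESeq2. IDO1, SPRR3, KRT13 and AFP were among 33 genes higher in Lep than in both Par and Int in at least 2 models (chance mean 24.5, permutation p = 0.053); these numbered 21 without LLC Int replicate 1 and 53 without LLC Lep replicate 3. HCC1954 and PC9 shared 195 higher (chance 88.1, permutation p = 0.001) and 264 lower genes (244, 0.07), with 414 opposite (342). HCC1954 and LLC shared 150 (95.5, 0.001) and 215 (173, 0.001), with 363 opposite (261), and PC9 and LLC 66 (45.7, 0.004) and 106 (108, 0.62), with 173 opposite (138). Opposite calls thus also exceeded their chance means, and Pearson correlations of fold changes were 0.04, 0.02 and -0.02 for these pairs. Differences between models were not tested.

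Lep and BrM were each compared with the same Par libraries, which makes their changes resemble each other by construction. In HCC1954, 927 genes were higher and 1461 lower in both, against 194 and 300 expected for independent calls, and 189 were opposite. In LLC the numbers were 402 and 898 against 87.9 and 250, with 120 opposite, and in PC9 153 and 106 against 44.5 and 38.1, with 180 opposite; MDA-MB-231 had 0 and 0, with 1 opposite. Covariances of the fold changes were 1.78, 0.72, 0.058 and 0.055 in HCC1954, LLC, PC9 and MDA-MB-231. Simulated shared Par libraries alone gave 0.016, 0.041, 0.016 and 0.067. The 3 Par libraries of a model were not divided between the comparisons.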

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

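The spread between MDA-MB-231 libraries of 1 group was examined with tests chosen only after it was seen. A length and GC bias of single libraries is a candidate explanation for part of it: the correction lowered the within-group SD by 24.3%, from 0.286 to 0.217, against 2.1% in HCC1954 and 7.66% in PC9, and most of the spread remained. Depth does not explain it, since 27.5% of genes at 1000 or more (2233 of 8107) differed over 2-fold between Par replicates 1 and 3, where counting error is small. Reads from another line of the series do not explain Par replicate 1 either: its CDH1 would require levels of that line's genes of which a median of only 2.09% was present. What else separates the libraries, such as culture or preparation day, is not given in the labels.

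The length dependence in PC9 was weighed with a gene-call test chosen only after the result was seen, and with a list test that was not. In PC9 Lep with Par, 63.1% of the called genes with a known length (1304 of 2067) stayed called after correction, so length and GC bias is not the whole cause but could account for calls among the rest. The median of the NF-kB list kept 94.7% of its value (0.86 before and 0.81 after, 23 genes). Because Int and Lep libraries lie on one side and Par and BrM on the other, a preparation difference cannot be told apart from stage in this model, and the correction may also remove real change that follows length.

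The rise of C3 in LLC Lep was set against host cells with tests chosen only after it was seen. The highest Lep mean among 4 macrophage genes was 193 for Lyz2, with Tyrobp at 1.7 and C1qa at 0.426, against 2150 for C3, so macrophages or microglia are unlikely as its main source. Fibroblasts that make type I collagen are unlikely as well, since the higher Lep mean of Col1a1 and Col1a2 was 29.7. The median of Col1a1, Col1a2, Col3a1, Dcn and Lum changed by -2.66 on average over Lep libraries, which decides nothing, because Col3a1 started from 112000 in Par and other markers of the set rose (Pdgfrb from 128 to 684). Pericytes and other host cells stay open. The growth of GFP-positive cells in culture before RNA was taken would lower the share of any host cells, but no value here measures it.

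In the 6 comparisons with 3 libraries in each group the real grouping was set against all other divisions of the same libraries into groups of the same size. The counts called were 4165 in HCC1954 Lep with Par, 68 in MDA-MB-231 BrM with Par, 1118 in PC9 BrM with Par, 2734 in LLC Lep with Par, 3136 in LLC BrM with Par and 2427 in LLC Lep with BrM. The highest count of any other division was 0 in each, and the real grouping was 1 of 10, too few divisions for a share under 0.05.

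Several results ran in opposite directions in different models in every library, which was not tested across tables. C3 in Int with Par differed by 6.82 on the log2 scale between LLC and HCC1954, and LCN2 in BrM with Par by 4.46 between HCC1954 and PC9. SLC22A17 differed between HCC1954 and LLC by 7.38 in Lep with Par, 6.99 in Lep with Int and 4.50 in Lep with BrM. Differences of list medians in Lep with Par were 1.09 for proliferation (LLC over MDA-MB-231) and 0.97 for p53 targets (MDA-MB-231 over LLC). In Lep with Int, HCC1954 exceeded MDA-MB-231 by 0.89 for complement and 1.89 for collagens, PC9 by 1.15 for NF-kB and 1.63 for mesenchymal genes, and LLC by 1.57 for adhesion. There MDA-MB-231 exceeded LLC by 1.27 for amino acid stress and PC9 exceeded MDA-MB-231 by 0.55 for semaphorins. Corrected for length and GC, neither semaphorin list nor MDA-MB-231 complement passed. In Int with Par, LLC exceeded HCC1954 by 2.40 for drug and redox defence. In BrM with Par, HCC1954 exceeded PC9 by 1.11 for NF-kB and LLC by 2.38 for antigen presentation, PC9 exceeded LLC by 1.96 for collagens and MDA-MB-231 by 1.67 for TGF-beta targets, and LLC exceeded PC9 by 1.2 for proliferation. In Lep with BrM, HCC1954 exceeded PC9 by 3.49 for mesenchymal genes, 2.08 for collagens, 0.74 for hypoxia, 2.09 for TGF-beta targets and 1.38 for adhesion, and LLC exceeded HCC1954 by 0.99 for antigen presentation.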

How the results depend on the processing

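MDA-MB-231 counts depended most on the choices made. Lep with Par (10 called) gave 16 with a pseudocount of 0.5, 4 with the 2 groups only, 81 with length and GC correction and 274 with DESeq2, and 3 to 112 over the libraries left out. Lep with Int (24) gave 70 with a pseudocount of 8, 15 with a filter at 50, 50 with quantile normalization, 0 with the 2 groups only, 99 with length and GC correction and 470 with DESeq2, and 2 to 369 over libraries. Int with Par (1049) gave 356 with the 2 groups only and 2170 with DESeq2, and 0 to 3845. BrM with Par (68) gave 43 with a filter at 50, 5 with the 2 groups only, 133 with length and GC correction, 109 with that correction and the block, and 471 with DESeq2, and 2 to 422. Lep with BrM (125) gave 72 without a filter, 62 with the block, 332 with length and GC correction and 740 with DESeq2, and 6 to 361.

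In the other models PC9 Lep with Int (88) gave 1 with the 2 groups only and 26 to 371 over libraries, and PC9 BrM with Par (1118) gave 735 with a filter at 50. LLC Int with Par (1548) gave 1004 to 1246 when an Int or Par library was left out. Genes called in at least 3 of 4 models (54) numbered 29 with a filter at 50 and 48 to 62 over libraries. Those higher in Lep than in Par and Int in at least 2 models (33) numbered 17 with a filter at 50 and 21 to 53 over libraries. The count in all 3 human models (0) was 1 with quantile normalization, 3 with length and GC correction, 13 with DESeq2 and up to 4 over libraries.

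Of the named genes, TMM scaling ended the call of 4 and a pseudocount of 0.5 that of 2. The only reversal was INSIG1 in PC9 Lep with Par without Lep replicate 2 (-0.07, and 2.31 without Lep replicate 1). Quantile normalization moved the median of all genes by over 0.1 in HCC1954 Int with Par (0.109) and LLC BrM with Par (0.111) only, and no list that had passed changed the sign of its median. Of the list results, an estimated correlation ended 136 calls, and all but 1 of the 48 it left had never passed. With fry 22 list calls ended and, in Lep with Par, 23 lists passed that had not. Lists that had not passed were counted in Lep with Par only. In MDA-MB-231 BrM with Par the block called 54 genes, 46 among the 68, and of named genes ended the call of NLRP2. Over all comparisons the block ended the calls of 14 named genes and 4 lists. It added 2 lists in Lep with Par, a count that leaves out lists added in other comparisons. The 2 groups only ended 57 gene calls, length and GC correction 30, no filter 17, a pseudocount of 8 and quantile normalization 14 each, edgeR 13, DESeq2 10 and a filter at 50 ended 7.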

Other observations

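In LLC, chosen after values were seen, the Hoxb and Hoxc clusters separated Lep from BrM. All 9 tested Hoxb genes were lower in Lep than in Par, with a median log2 fold change of -6.87, and Hoxb2 and Hoxb3 were listed at 0 in every Lep library against 312 ± 8.44 and 332 ± 14.6 in Par. BrM kept both, at 398 ± 67.4 and 350 ± 8.2. BrM lost all 6 tested Hoxc genes, with Hoxc6 at 2.25 ± 1.01 against 125 ± 15.9 in Par and 228 ± 16.8 in Lep. The others were at 0 in BrM. Of 11 Hoxa genes 2 fell in Lep and 3 rose in BrM.

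In HCC1954, also chosen after values were seen, many genes were at 100 or more in every Par library and at 5 or less in every library of a derivative. They numbered 162 in Int, 130 in Lep and 133 in BrM, and 95 of the 190 in any were off in all 3. The reverse, off in Par and on in a derivative, held for 30 genes. MDA-MB-231 had 0 genes off in any derivative, PC9 1, 1 and 2, and LLC 3, 29 and 29.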
